A study of Mus musculus with 12 samples.

How the data were processed

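Hippocampal RNA of 12 mouse libraries was measured, 4 in each of the groups siScramble, siHdac4 and siBdnf. Per the labels' protocols, RNA was taken with TRIzol and made into poly-A selected, strand-specific libraries. The submitters' processing notes name TopHat2 2.0.9, Cufflinks and Cuffdiff, with no version for the last 2. The genome build and the annotation were not given in the sources used here. Of 11441 protein-coding loci with a single gene of the same name in the mouse annotation used for comparison (GENCODE on GRCm38), 11290 (98.7%) overlapped that gene, and 4.55% shared a start or an end within 1 base. Coordinates are printed as the deposited tables give them.

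The authors deposited 2 tables of 22306 loci, with FPKM values per library, one for each siRNA group beside siScramble. The 4 siScramble columns were identical in both. How FPKM values were scaled between libraries is not given in the sources used here. The deposited log2 fold change equalled the ratio of the group means to within 9.4e-06 at 20954 loci of the siHdac4 table, compared only where the authors' p was below 1. The authors' p-value and FDR per locus were used only where the authors' deposited table is named, and the smallest deposited p was 5e-05. Every value column belonged to 1 of the 12 libraries or to the authors' comparisons.

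FPKM values are not counts, so limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1), with a trend of the prior variance on the mean, at loci with a mean of at least 1 FPKM over the 12 libraries. All 3 groups entered the same fit without covariates, and the Benjamini-Hochberg adjusted p had to lie below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low level. Every adjusted p in the text comes from limma or, for lists, from camera in limma. The targets were also tested by an exact permutation of 4 against 4 libraries with scipy 1.17.1. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9.

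The design, the 32 gene lists and the rule for named genes were fixed before the data were examined. The lists cover neuronal, glial, vascular and neighbouring tissue markers, synaptic, signalling, metabolic and immune genes. They were tested with camera at a preset correlation of 0.01 and adjusted over the lists. The rule named both targets and, per comparison, the 10 most raised and 10 most lowered genes past the threshold. It also named up to 4 members of smallest p in each list described, and up to 5 genes per direction that passed in both comparisons. Predicted genes and small RNAs were left out of the names, and Rn7sk, Gm10800 and the lincRNA on chromosome 9 were named after their values were seen. Genes quoted from the authors' deposited table were chosen after their values were seen. The list tests between siHdac4 and siBdnf were added after the data were seen.

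Several loci were listed at 0 in all 4 libraries of a group while another group was at 1 FPKM or more and the authors' p was 1. There were 47 of them, 40 named Celf2. The design did not foresee them, so the results include them, and a fit without them was added after they had been called. Other alternatives added after the data were seen left out siScramble libraries 1 and 3, left out siScramble libraries 3 and 4 from the list tests, kept protein-coding loci only, used robust or untrended prior variances, added the choroid plexus level as a covariate, or corrected each library for transcript length and GC content. For the lists, further scalings, thresholds, pseudocounts and left-out libraries were added as well. Length and GC content, taken from the longest GENCODE transcript of each gene, were known for 97.2% of the protein-coding loci tested. The alternatives set beforehand were another pseudocount, other filters, quantile and median scaling, the 2 groups alone, a replicate block, library weights, other thresholds, a minimum change, an estimated correlation and leaving out each library in turn.

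The fit was tested on normal values simulated from its own means and variances. In a simulation of siHdac4 against siScramble at 18387 loci, limma called 44% of 50 loci changed by 0.5 on the log2 scale and 88% of 50 changed by 1. It called 98% of 50 changed by 2 and 100% of 50 changed by 4, with 3 false calls. In the same simulation it called 0 loci for siBdnf against siScramble, where no locus was changed. The simulated loci were independent and had the same variance in each group, while the median SD of the libraries was 0.175 in siScramble, 0.133 in siHdac4 and 0.120 in siBdnf. The number of false calls need not hold for the data. Depth in reads was not part of the tables. Relative depth was read from the step between values under 2 FPKM and was accepted for 9 of the 11 libraries compared with siScramble library 1, where 2 sets of loci and all loci agreed within 0.06 on the log2 scale. Shared controls were handled by 100 simulations of unchanged groups against the same siScramble libraries.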

Results

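RNA was sequenced from the hippocampus of C57BL/6 mice that had received 10 µg of a small interfering RNA (siRNA) through the nose and were killed 3 days later. The 12 libraries formed 3 groups of 4, labelled siScramble (a control sequence), siHdac4 (against histone deacetylase 4) and siBdnf (against brain-derived neurotrophic factor). Each of the 22306 loci carried an FPKM value per library, and 18387 loci with a mean of at least 1 FPKM were tested, of which 11061 were protein-coding. Read totals were not part of the tables. From the step between low values, the worth of 1 read relative to siScramble library 1 ran from 0.801 in siBdnf library 4 to 1.32 in siScramble library 2, and was 1.13 in siHdac4 library 2. A higher worth means fewer reads only if the libraries were scaled alike, which is not known. The estimate was not resolved for siScramble library 3 and siBdnf library 1. The labels do not say whether each library came from its own animal, so the p-values measure the spread between these libraries, which may be partly technical.

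The first comparison asked whether the 2 targeted transcripts were lower in the libraries labelled with their siRNA. Hdac4, a class IIa histone deacetylase, was at 39.1 ± 5.94 FPKM in siScramble, 41.0 ± 5.93 in siHdac4 and 39.998 ± 3.69 in siBdnf (SD, n = 4 each). Its single values in siScramble were 45.9, 31.5, 40.6 and 38.6 FPKM, in siHdac4 34.0, 48.2, 39.6 and 42.3 FPKM, and in siBdnf 35.9, 44.8, 39.1 and 40.2 FPKM. Bdnf, a secreted ligand of the TrkB receptor, was at 5.37 ± 0.174 FPKM in siScramble, 5.73 ± 0.591 in siHdac4 and 5.19 ± 0.255 in siBdnf (SD, n = 4 each). Its single values in siScramble were 5.33, 5.51, 5.14 and 5.50 FPKM, in siHdac4 5.94, 6.46, 5.38 and 5.15 FPKM, and in siBdnf 5.19, 4.84, 5.29 and 5.43 FPKM.

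Neither target differed from siScramble by more than the spread between libraries. The log2 fold change of Hdac4 in the libraries labelled siHdac4 was 0.067 (95% interval −0.20 to 0.34; limma adjusted p = 0.863; exact two-sided permutation p = 0.657). For Bdnf in the libraries labelled siBdnf it was −0.043 (95% interval −0.21 to 0.12; limma adjusted p = 0.906; exact two-sided permutation p = 0.286). The smallest p that 4 against 4 libraries can give is 0.0286. In the authors' deposited table Hdac4 had a log2 fold change of 0.067 in siHdac4 and Bdnf one of −0.0505 in siBdnf, both with an FDR of 1.00. The sign of the Hdac4 value turned without siScramble replicate 2 (−0.031) and without siHdac4 replicate 2 (−0.013). The groups are therefore named by their labels in all that follows, because transcript levels did not separate the targeted groups from the controls.

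**Figure D1:**
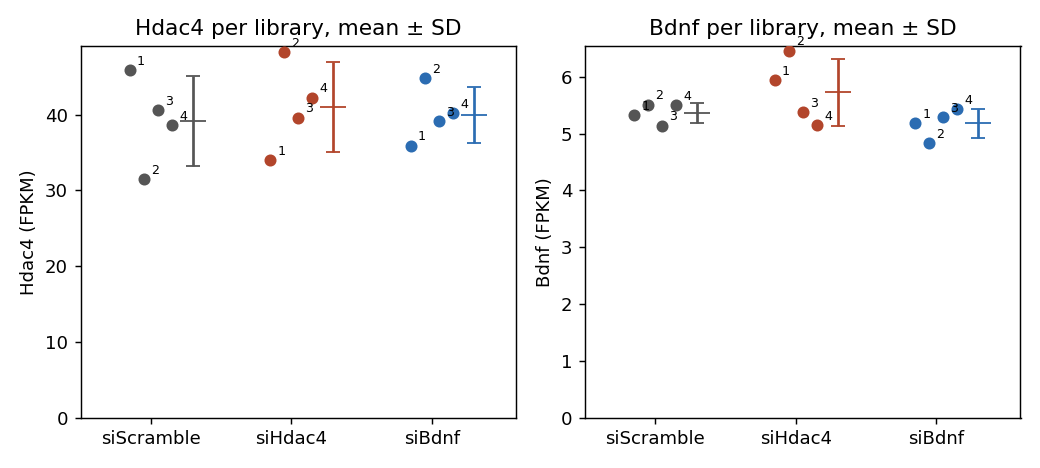
Each point is the FPKM of Hdac4 (left) or Bdnf (right) in 1 of the 12 libraries, numbered by replicate, on an axis that starts at 0, with the mean and SD of each group beside the points. Hdac4 lay between 31.5 and 48.2 FPKM and Bdnf between 4.84 and 6.46 FPKM over all libraries, with the groups overlapping.

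The second comparison set the libraries labelled siHdac4 against siScramble. Hfe, which regulates iron uptake, fell by 0.64 on the log2(FPKM + 1) scale, from 2.10 ± 0.280 to 0.987 ± 0.226 FPKM (SD, n = 4 each; limma adjusted p = 0.0112). Lgals3bp, a secreted galectin-binding glycoprotein of the interferon-stimulated list, fell by 0.76, from 3.46 ± 0.713 to 1.60 ± 0.160 FPKM (limma adjusted p = 0.0287). Ikzf4, a zinc-finger transcription factor of the Ikaros family, fell by 0.41, from 2.03 ± 0.0999 to 1.28 ± 0.170 FPKM (limma adjusted p = 0.0426). Polr2f, a subunit shared by the nuclear RNA polymerases, rose by 0.92, from 35.3 ± 2.33 to 68.4 ± 12.1 FPKM (limma adjusted p = 0.0391). An unannotated lincRNA on chromosome 9 (124154857 to 124330758), outside the naming rule and chosen after its values were seen, rose by 0.78, from 39.6 ± 4.34 to 68.4 ± 6.62 FPKM (limma adjusted p = 0.000713). The authors' deposited table gave it an FDR of 0.591. In siBdnf each of these moved the same way against the same controls, without passing. The log2 fold changes there were −0.32 for Hfe, −0.54 for Lgals3bp, −0.062 for Ikzf4, 0.20 for Polr2f and 0.36 for the lincRNA.

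These genes were among 48 loci past an adjusted p of 0.05 in limma, 4 higher and 44 lower, and 1865 loci (829 higher, 1036 lower) lay under an unadjusted p of 0.05 where 919 were expected by chance. Of the 48, 41 were listed at 0 through a whole group, 40 of them under the name Celf2 and the other under Rn7sk. The protein-coding locus of Celf2, an RNA-binding splicing regulator, lies on chromosome 2 (6532897 to 7396612) and the other 39 loci of that name carry the same coordinates and are annotated as intronic. Its siScramble values were 102, 91.8, 99.6 and 105 FPKM, and it was listed at 0 in each of the 8 libraries labelled siHdac4 or siBdnf. The authors' deposited table gave a p of 1 and a log2 fold change of 0 at all 40 of these loci. A measured 0 against these siScramble values would not give a fold change of 0, which argues that the zeros are values that were not estimated. Rn7sk, the small nuclear RNA of the P-TEFb complex, was at 35879, 9798, 16102 and 22348 FPKM in siScramble and was listed at 0 in all 8 others.

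With the 47 loci listed at 0 through a group left out, an alternative chosen after those calls had been seen, 1 locus remained past the threshold, the lincRNA on chromosome 9 (adjusted p = 0.0295), and 1826 lay under an unadjusted p of 0.05. Hfe then had an adjusted p of 0.239, and Lgals3bp, Ikzf4 and Polr2f one of 0.289. With protein-coding loci alone the adjusted p was 0.193 for Hfe, Lgals3bp and Polr2f and 0.339 for Ikzf4. The 12 fits that left out a single library all kept the loci listed at 0, so they do not test whether a call rests on those loci. Hfe kept its call in all 12, while Lgals3bp kept it in 4, Polr2f in 4 and Ikzf4 in 2 of them. The highest adjusted p for Lgals3bp was 0.126 without siHdac4 replicate 2, for Polr2f 0.146 without siHdac4 replicate 1, and for Ikzf4 0.173 without siHdac4 replicate 2. Without siScramble replicate 1 the count of loci was 248.

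Among the 32 gene lists, 5 passed in the libraries labelled siHdac4 under a preset correlation between genes of 0.01, and none of the 5 did with an estimated correlation. The oxidative phosphorylation list, which holds subunits of the mitochondrial respiratory chain, rose, with 52 of 63 members above 0 and a median log2 fold change of 0.15 (adjusted p = 6.71e-09). With an estimated correlation its adjusted p = 0.412. Cytosolic ribosomal proteins rose too, with 50 of 65 members above 0 and a median of 0.15 (adjusted p = 4.32e-06; adjusted p = 0.486 with an estimated correlation). In limma 0 members of either list passed over all loci or adjusted over the list alone, and 15 and 11 of them were higher at an unadjusted p under 0.05. Cox6b1, a subunit of cytochrome c oxidase, was at 411 ± 84.8 FPKM in siScramble and 548 ± 72.1 FPKM in siHdac4 (log2 fold change 0.43 ± 0.14, SE, limma adjusted p = 0.445). Atp5c1, a subunit of ATP synthase, had a log2 fold change of 0.26 and Uqcrc2, a subunit of complex III, one of 0.16. Of the ribosomal proteins, Rpl35 had a log2 fold change of 0.46, Rps19 of 0.32 and Rpl32 of 0.29, none past the threshold. Without siScramble replicate 1, Rpl35 (log2 fold change 0.57, adjusted p = 0.0192), Rpl32 (0.38, adjusted p = 0.0273) and Cox6b1 (0.56, adjusted p = 0.040) passed over all loci. The oxidative phosphorylation level of siScramble library 1, 6.10 in mean log2(FPKM + 1), lay among those of siHdac4, and those of siScramble libraries 3 and 4 were the lowest of the 12, at 5.84 and 5.82.

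Across 10750 genes the log2 fold change was lower for longer transcripts (Spearman −0.19), and genes are not independent replicates. The correlation of level relative to the 12 libraries with transcript length was −0.10, −0.002, 0.16 and 0.18 in siScramble libraries 1 to 4. In siHdac4 libraries 1 to 4 it was −0.078, −0.076, −0.18 and −0.084. Without siScramble libraries 3 and 4 the medians were 0.088 for oxidative phosphorylation (adjusted p = 0.0999) and 0.080 for ribosomal proteins (adjusted p = 0.254).

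Choroid plexus and ependymal markers, genes of the cells that secrete and move the cerebrospinal fluid, fell, with 19 of 19 members below 0 and a median of −1.03 (adjusted p = 1.63e-07; adjusted p = 0.486 with an estimated correlation). In limma 0 of them passed over all loci or adjusted over the list alone, and 9 were lower at an unadjusted p under 0.05. Ttr, the thyroid hormone carrier made by choroid plexus, was at 810, 17.9, 1977 and 9.99 FPKM in siScramble libraries 1 to 4, and between 7.91 and 63.3 FPKM in siHdac4. The high level thus lay in siScramble libraries 1 and 3, and without them the median of the list was −0.076 (adjusted p = 0.709). Dynlrb2, a dynein light chain of cilia, was at 4.58 ± 1.46 FPKM in siScramble and 2.47 ± 0.684 FPKM in siHdac4 (limma adjusted p = 0.397), and Foxj1, a regulator of motile cilia, at 2.57 ± 1.38 and 1.18 ± 0.498 FPKM (limma adjusted p = 0.446).

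Cholesterol synthesis genes rose, with 18 of 20 members above 0 and a median of 0.10 (adjusted p = 0.00435; adjusted p = 0.427 with an estimated correlation). Insig1, a sensor of sterols, had a log2 fold change of 0.22, Mvk, mevalonate kinase, of 0.40 and Fdft1, squalene synthase, of 0.22, none past the threshold. Interferon-stimulated genes fell, with 16 of 18 members below 0 and a median of −0.15 (adjusted p = 0.0359; adjusted p = 0.412 with an estimated correlation). Lgals3bp passed over all loci, and with Dhx58, a cytosolic RNA sensor, 2 members passed adjusted over the list alone. Dhx58 was at 1.502 ± 0.719 FPKM in siScramble and 0.309 ± 0.342 FPKM in siHdac4. B2m, the light chain of class I histocompatibility molecules, had a log2 fold change of 0.21 (limma adjusted p = 0.556). The mean level of the interferon list was highest in siScramble libraries 1 and 3, the 2 with high choroid plexus transcripts, at 2.61 and 2.51 in log2(FPKM + 1), and without them its median was −0.066 (adjusted p = 0.795). Without them the cholesterol median was 0.046 (adjusted p = 0.26). Leaving out siScramble replicate 3 alone ended both calls (adjusted p = 0.0604 for each), and the interferon call also ended without siScramble replicate 1 (median −0.11, adjusted p = 0.547). It ended without siHdac4 replicate 2 (adjusted p = 0.0765) or 4 (adjusted p = 0.0916) too, although the medians were then farther from 0 (−0.17 and −0.16). It ended as well with filters of 5 FPKM (adjusted p = 0.90) and 0.1 FPKM (adjusted p = 0.256).

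Lists tied to the targets did not pass in the planned fit. The median log2 fold change was −0.043 for 29 TrkB and neurotrophin pathway genes (adjusted p = 0.764), 0.0065 for 23 histone deacetylases and partners (adjusted p = 0.761) and 0.097 for 34 activity-regulated genes (adjusted p = 0.077). Glutamate receptor and postsynaptic density genes had a median of −0.060 (adjusted p = 0.0948) and GABA system genes one of 0.042 (adjusted p = 0.358). The activity-regulated list passed, under the preset correlation, without siScramble replicate 1 (median 0.18, adjusted p = 0.00487), siScramble replicate 2 (0.16, adjusted p = 0.0195) or siHdac4 replicate 1 (0.13, adjusted p = 0.0415). It also passed without siScramble libraries 1 and 3 (0.14, adjusted p = 0.0222) and with a filter of 0.1 FPKM (adjusted p = 0.0465), and the glutamate receptor list passed with protein-coding loci only (adjusted p = 0.0323).

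**Figure D2:**
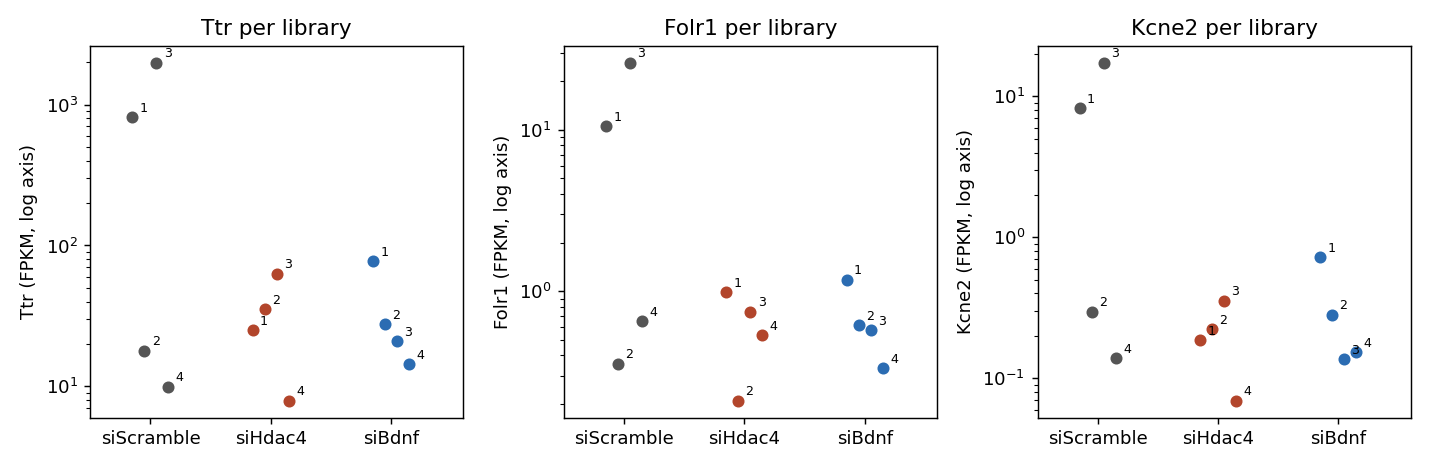
Each point is the FPKM of Ttr, Folr1 or Kcne2, 3 choroid plexus markers, in 1 library, numbered by replicate, on a logarithmic axis. For each gene siScramble libraries 1 and 3 stand above the 10 other libraries, with 810 and 1977 FPKM of Ttr against at most 77.1 FPKM elsewhere.

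**Figure D3:**
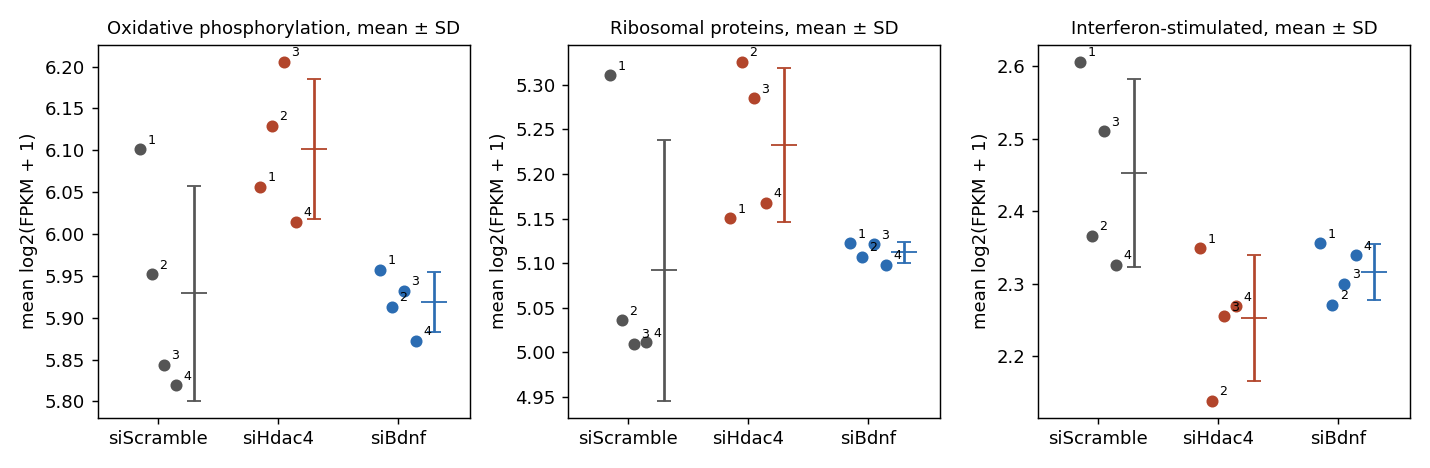
Each point is the mean log2(FPKM + 1) of a gene list in 1 library, numbered by replicate, with the mean and SD of each group beside the points; the axes do not start at 0. Oxidative phosphorylation ran from 6.01 to 6.21 in siHdac4 and from 5.82 to 6.10 in siScramble, where library 1 lay among the siHdac4 libraries.

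The third comparison set the libraries labelled siBdnf against siScramble. Wasf1, an actin regulator of the WAVE complex in neurons, fell by 0.53 on the log2(FPKM + 1) scale, from 27.9 ± 2.596 to 19.0 ± 1.96 FPKM (SD, n = 4 each; limma adjusted p = 0.0301). Cpd, carboxypeptidase D, fell by 0.61, from 24.6 ± 0.985 to 15.8 ± 0.366 FPKM (limma adjusted p = 0.0272). Cfap52, a protein of motile cilia, fell by 0.60, from 2.80 ± 0.483 to 1.49 ± 0.144 FPKM (limma adjusted p = 0.0157). Zfp69, a zinc-finger protein, rose by 0.66, from 0.600 ± 0.198 to 1.52 ± 0.296 FPKM (limma adjusted p = 0.0264). Intronic loci within Cadm2, a synaptic adhesion gene, Cblb, a ubiquitin ligase gene, and Rasal2, a Ras GTPase-activating gene, rose by 0.75, 0.80 and 0.67 (limma adjusted p = 0.0162, 0.0233 and 0.0218). The median deviation of all 3343 intronic loci from their mean over the 12 libraries ran from 0.034 to 0.18 in siBdnf and from −0.15 to 0.10 in siScramble. The named intronic loci were not tested against that class. In siHdac4 each gene and intronic locus named here moved the same way against the same controls, without passing. The log2 fold changes there were −0.26 for Wasf1, −0.42 for Cpd, −0.41 for Cfap52 and 0.35 for Zfp69. For the loci within Cadm2, Cblb and Rasal2 they were 0.12, 0.35 and 0.15.

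The genes and intronic loci named above were among 51 loci past the threshold, 5 higher and 46 lower. At an unadjusted p under 0.05 the balance was the opposite, with 1051 of 1627 loci higher and 576 lower. Of the 51, 43 were listed at 0 through a whole group, namely the 40 loci named Celf2, Rn7sk and 2 loci named Gm10800. The protein-coding locus of Gm10800 was at 1388, 3056, 9410 and 11468 FPKM in siScramble and was listed at 0 in all 4 libraries labelled siBdnf. With loci listed at 0 through a group left out, limma called 0 loci, with a smallest adjusted p of 0.191 and 1581 loci under an unadjusted p of 0.05. With protein-coding loci alone the adjusted p was 0.13 for Wasf1, Cpd and Cfap52 and 0.247 for Zfp69. Of the 12 fits that left out a single library, Cfap52 kept its call in 8, Rasal2 in 7, Cadm2 and Cblb in 6 each, Wasf1 in 4, and Cpd and Zfp69 in 3 each. These fits kept the loci listed at 0. The highest adjusted p was 0.146 for Wasf1 without siBdnf replicate 4, 0.118 for Cpd without siBdnf replicate 2, 0.105 for Zfp69 without siScramble replicate 1 and 0.0734 for Cfap52 without siBdnf replicate 2. For the intronic loci it was 0.0751 for Cadm2 without siBdnf replicate 3, 0.0981 for Cblb without siBdnf replicate 1 and 0.0989 for Rasal2 without siBdnf replicate 2.

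Choroid plexus and ependymal markers were the 1 list that passed, with 18 of 19 members below 0 and a median of −0.87 (adjusted p = 1.16e-07; adjusted p = 0.663 with an estimated correlation). In limma 0 members passed over all loci and 1 passed adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Dynlrb2 was at 4.58 ± 1.46 FPKM in siScramble and 2.01 ± 0.469 FPKM in siBdnf (limma adjusted p = 0.227). Kcne2, a potassium channel subunit of choroid plexus, was at 8.22, 0.298, 17.3 and 0.139 FPKM in siScramble libraries 1 to 4 and at most 0.723 FPKM in siBdnf. Without siScramble libraries 1 and 3 the median of the list turned to 0.056 (adjusted p = 0.982), and the log2 fold change of Kcne2 to 0.10. The protein folding and heat shock list passed in that fit under the preset correlation (median 0.196, camera adjusted p = 0.000346). In the planned fit it had a median of 0.049 (camera adjusted p = 0.362).

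Extracellular matrix genes had a median of −0.076 (adjusted p = 0.0622) and interferon-stimulated genes one of −0.11 (adjusted p = 0.0656). Sparc, a matrix glycoprotein, was at 69.8 ± 6.36 FPKM in siScramble and 56.9 ± 2.58 FPKM in siBdnf (limma adjusted p = 0.227), and it passed adjusted over the list alone. Without siScramble replicate 4 Sparc also passed over all loci (log2 fold change −0.35, adjusted p = 0.0172). The TrkB and neurotrophin pathway list had a median of −0.0355 (adjusted p = 0.404), and within it Ntrk2, the receptor of Bdnf, was at 265 ± 24.0 FPKM in siScramble and 235 ± 13.7 FPKM in siBdnf (limma adjusted p = 0.564). Activity-regulated genes had a median of 0.080 (adjusted p = 0.362), with Arc, a synaptic immediate early gene, at 23.4 ± 7.47 and 29.3 ± 5.80 FPKM. Without siScramble replicate 1 the activity-regulated list passed (median 0.12, adjusted p = 0.0217), as did ribosomal proteins (0.069, adjusted p = 0.0123) and the matrix list (−0.097, adjusted p = 0.0221). These list calls and those that follow used the preset correlation. With an estimated correlation in the planned fit the camera adjusted p was 0.91, 0.932 and 0.386 for these lists and 0.563 for the interferon list. Without loci listed at 0 the matrix and interferon lists passed (adjusted p = 0.0296 and 0.0338). The matrix list also passed without siHdac4 replicate 2 (adjusted p = 0.0442), siBdnf replicate 1 (0.0302) or siBdnf replicate 2 (0.029). The interferon list did without siScramble replicate 2 (adjusted p = 0.0378) or 4 (0.0165), siHdac4 replicate 2 (0.0442), or siBdnf replicate 1 (0.0302) or 3 (0.0492). It did not pass without siScramble replicate 1, without replicate 3 or without both. Its level in log2(FPKM + 1) was 2.61 and 2.51 in siScramble libraries 1 and 3. In siScramble libraries 2 and 4 it was 2.37 and 2.33, near the 2.27 to 2.36 of siBdnf. Oxidative phosphorylation and ribosomal proteins had medians of 0.0049 and 0.019 (adjusted p = 0.789 and 0.827). Without siScramble libraries 3 and 4 the oxidative phosphorylation list was lower in siBdnf under the preset correlation (median −0.099, adjusted p = 0.0103). With an estimated correlation in the planned fit its camera adjusted p was 0.932.

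**Figure D4:**
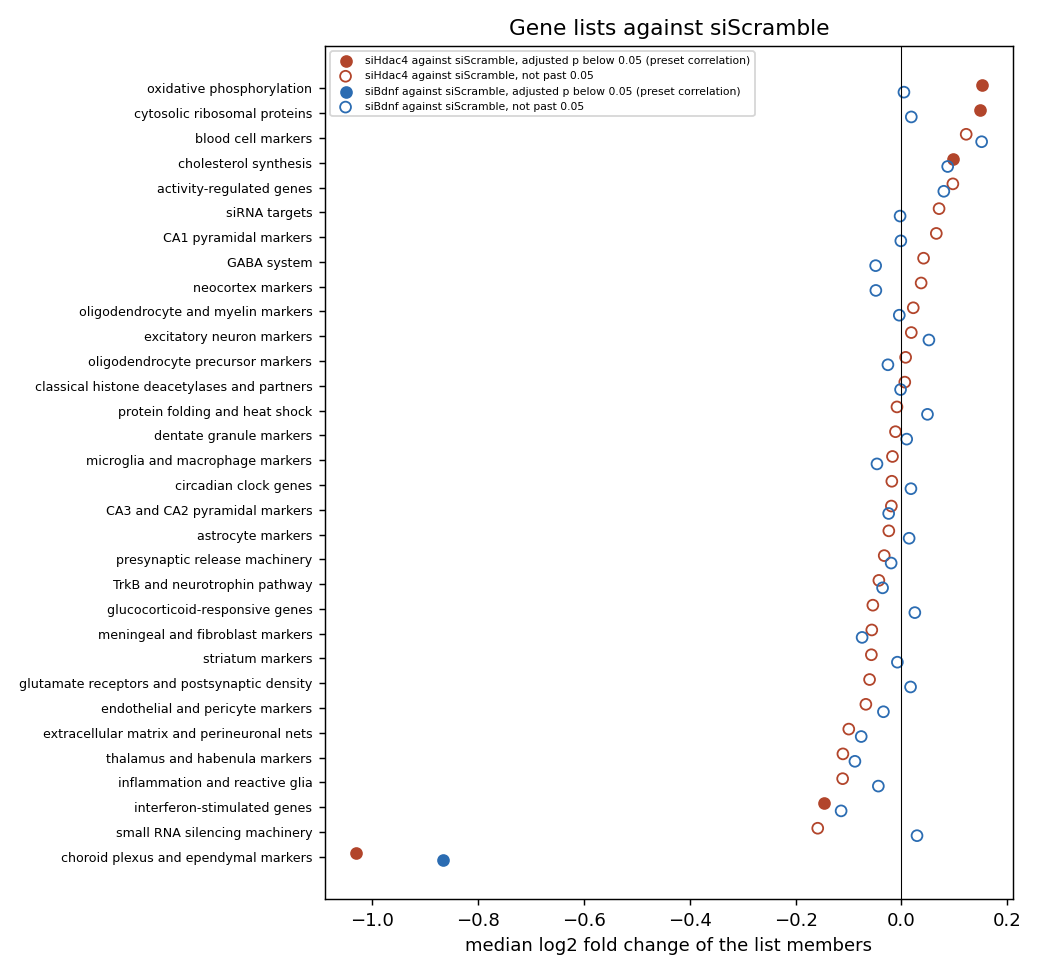
Each point is the median log2 fold change of the tested members of 1 of 32 gene lists, for siHdac4 (red) and siBdnf (blue) against siScramble; filled points passed an adjusted p of 0.05 with a preset correlation between genes. The choroid plexus list lies farthest from 0, at −1.03 and −0.87, and no list passed with an estimated correlation.

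The series title asks for targets common to both siRNAs. Celf2 and Rn7sk, listed at 0 in both groups, made up the 41 loci that passed in both comparisons, all lower, with 0 higher and 0 in opposite directions. Of independent lists, 0.11 shared lower loci were expected, and of unchanged groups simulated against the same controls 0.24. The 40 Celf2 loci share the same coordinates, and a locus listed at 0 in both groups enters both comparisons alike. The excess over these numbers is therefore no evidence of common targets. With loci listed at 0 through a group left out, limma called 0 loci in both, while 158 were higher and 155 lower in both at an unadjusted p under 0.05, against 257 and 261 in the simulation and 47.4 and 28.9 of independent lists. In opposite directions there were 10 such loci, above the simulated range of 0 to 8 (mean 3.63) and below the 81.1 of independent lists. Between the 2 fold changes, over all 18387 loci, Pearson's r was 0.65 and Spearman's rho 0.23, against 0.67 and 0.58 in the simulation, across loci that are not independent replicates. Without the loci listed at 0, r was 0.24 and the covariance 0.0122, below the simulated 0.671 and 0.0257. When the controls were split, with 2 for each comparison, r without those loci ranged from −0.47 to 0.15.

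Choroid plexus genes, none of which passed over all loci here, were among the shared calls of the authors. By the authors' deposited table, 221 loci had an FDR under 0.05 in siHdac4 (52 higher, 169 lower) and 141 in siBdnf (34 higher, 107 lower). The authors' deposited table called 62 loci lower and 4 higher in both and 10 in opposite directions, against 0.81 shared lower loci expected of independent lists. Of those 62 loci in the authors' deposited table, 47 had siScramble libraries 1 and 3 as the 2 highest controls. If each pair of controls were equally likely to be highest, 16.7% of loci would, and the share over all loci was not counted. Among all lower calls of the authors, 59 of 169 in siHdac4 and 57 of 107 in siBdnf did. Ttr had a log2 fold change of −4.42 in siHdac4 and −4.33 in siBdnf in the authors' deposited table, and Kcne2 −4.96 and −4.33. Cpd, which is not a choroid plexus list member, was also called lower in both in the authors' deposited table (FDR 0.00739 in each). It was at 24.6 ± 0.985 FPKM in siScramble, 18.4 ± 3.62 in siHdac4 and 15.8 ± 0.366 in siBdnf (SD, n = 4 each). In limma its log2 fold change was −0.42 in siHdac4 (adjusted p = 0.299) and −0.61 in siBdnf (adjusted p = 0.0272). Both comparisons used the same siScramble libraries, so part of the overlap of the authors' calls may come from them.

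The last comparison set the libraries labelled siHdac4 directly against those labelled siBdnf. Hn1, a small microtubule-associated protein gene, was higher in siHdac4, at 38.2 ± 2.87 against 20.7 ± 0.504 FPKM (SD, n = 4 each; log2 fold change 0.85, limma adjusted p = 0.0364). Sugct, a mitochondrial CoA transferase, was lower, at 2.62 ± 0.404 against 4.80 ± 0.389 FPKM (log2 fold change −0.69, limma adjusted p = 0.0291). Ssxb2, a gene of the SSX family on chromosome X, was lower, at 0.564 ± 0.0900 against 1.96 ± 0.315 FPKM (log2 fold change −0.92, limma adjusted p = 0.0112). It belongs to a family of near-identical copies, so its reads may be shared between them. In siScramble these genes were at 25.9 ± 5.40, 3.56 ± 0.117 and 0.994 ± 0.225 FPKM.

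With the 2 Gm10800 loci listed at 0 in siBdnf, named after their values were seen, these made 5 loci past the threshold, 3 higher and 2 lower, and of 2865 loci under an unadjusted p of 0.05, 946 were higher and 1919 lower. Without the loci listed at 0, Ssxb2 alone passed (adjusted p = 0.0334), with 0.0583 for Sugct and 0.060 for Hn1. With protein-coding loci alone all 3 genes passed (adjusted p = 0.0168 for each). Of the 12 fits that left out a single library, Ssxb2 kept its call in 6, Sugct in 4 and Hn1 in 3. These fits kept the loci listed at 0. The highest adjusted p was 0.0718 for Ssxb2 without siBdnf replicate 2, 0.131 for Sugct without siBdnf replicate 1 and 0.21 for Hn1 without siHdac4 replicate 2. Single libraries moved the count from 2 (without siHdac4 replicate 3, siBdnf replicate 2 or siBdnf replicate 4) to 23 (without siScramble replicate 1), and it was 3 without siHdac4 replicate 1 or 2 or siBdnf replicate 1 or 3. With limma's library weights it was 103 (39 higher, 64 lower), and with the 2 groups alone in the fit it was 152 (46 higher, 106 lower). The siScramble libraries had the widest spread, with a median SD of 0.175 in log2(FPKM + 1) against 0.133 in siHdac4 and 0.120 in siBdnf.

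Oxidative phosphorylation genes were higher in siHdac4 than in siBdnf, with 47 of 63 members above 0 and a median of 0.17 (adjusted p = 3.09e-08; adjusted p = 0.573 with an estimated correlation). In limma 0 of them passed over all loci or adjusted over the list alone, and 21 were higher at an unadjusted p under 0.05. The level of the list ran against the median level of intronic loci across the 12 libraries (Spearman −0.92), and also within the groups (Pearson −0.92 for deviations from the group means), a comparison chosen after both had been seen. Ndufs8, a subunit of complex I, was at 40.2 ± 4.36 FPKM in siHdac4 and 31.3 ± 2.07 FPKM in siBdnf, and Atp5e, a subunit of ATP synthase, at 61.6 ± 11.9 and 38.4 ± 6.64 FPKM (limma adjusted p = 0.212 for each). Ribosomal proteins were higher, with 49 of 65 members above 0 and a median of 0.14 (adjusted p = 8.25e-05; adjusted p = 0.668 with an estimated correlation). After correction for transcript length and GC content the ribosomal median was 0.086 (adjusted p = 0.439). Rpsa, a protein of the small ribosomal subunit, was at 121 ± 17.7 and 81.6 ± 5.31 FPKM (limma adjusted p = 0.21; 0.0448 with library weights). Neocortex markers were higher, with 12 of 18 members above 0 and a median of 0.089 (adjusted p = 0.028; adjusted p = 0.584 with an estimated correlation). That call ended without siScramble replicate 1 (adjusted p = 0.0545), siHdac4 replicate 2 (0.0531) or siBdnf replicate 4 (0.151). At a mean of at least 5 FPKM the neocortex median was −0.0013 (adjusted p = 0.813). The call also ended at 0.1 FPKM (adjusted p = 0.0591), with protein-coding loci only (median still 0.089, adjusted p = 0.0837) and after the length and GC correction, although the median rose to 0.13 (adjusted p = 0.111). Lamp5, a membrane protein of upper-layer cortical neurons, was at 10.9 ± 1.07 FPKM in siHdac4 and 9.08 ± 1.31 FPKM in siBdnf.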

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

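All tests of explanations in this part were chosen after the results were seen, and the bounds for them and for the other splits were written then too.

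Choroid plexus and ependymal genes were lower in both siRNA groups. In 14 of 19 list members siScramble libraries 1 and 3 were the 2 highest of the 12 libraries, among them Ttr at 810 and 1977 FPKM and Enpp2 at 229 and 577 FPKM. The tables argue against both siRNAs lowering these genes from a level shared by all controls, because only 2 of the 4 siScramble libraries lay above the highest siRNA library in the list level (3.39 and 4.64 against 2.37), and the other 2 lay at 1.93 and 1.90. More choroid plexus tissue in siScramble libraries 1 and 3 is a candidate explanation that these values meet, found and tested on the same data. Of the 19 members, 3 stand in another list too and 13 had a mean of at least 1 FPKM over the 8 siRNA libraries.

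Oxidative phosphorylation and ribosomal protein genes were higher in siHdac4, and their levels ran against that of intronic loci over the 12 libraries (Spearman −0.92 and −0.82) and within groups (Pearson −0.92 and −0.79). For siHdac4 against siScramble the medians after correction for transcript length and GC content were 0.13 for oxidative phosphorylation and 0.11 for ribosomal proteins. Both lists were still past the threshold, under the preset correlation only. These medians argue against such a trend as the whole cause there only as far as the lengths used hold. Length and GC content came from the longest GENCODE transcript of each gene, which may differ from the deposited loci, so part of a trend may remain. Against siBdnf the same correction ended the ribosomal call (median 0.14 before and 0.086 after, adjusted p = 0.439). That siScramble libraries 3 and 4 stand apart stays open, since the medians without them, 0.088 and 0.080, neither vanished nor kept both lists past the threshold. An effect of the Hdac4 siRNA cannot be told apart from the spread of the controls, because 2 of the 4 siHdac4 libraries lay above every siScramble library in the oxidative phosphorylation level, siScramble library 1 lay above the other 2, and Hdac4 itself was not lower. Against siBdnf, a difference that uses no siScramble level, all 4 siHdac4 libraries (6.01 to 6.21) lay above all 4 siBdnf libraries (5.87 to 5.96), so siScramble libraries 3 and 4 do not account for that part; it was lost with an estimated correlation (adjusted p = 0.573), and since the intronic level parted the same 8 libraries (−0.12 to −0.026 against 0.034 to 0.18), a difference in RNA or library composition stays open, as untested.

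Loci named Celf2 were listed at 0 in both siRNA groups. All 40 had a p of 1 in both comparisons of the authors' deposited table, as values not estimated by the authors' software would, and the 40 share the same coordinates. The authors' deposited table also gave these loci a log2 fold change of 0, although the protein-coding one was at a mean of 99.7 FPKM in siScramble. A measured 0 against that mean would not give a fold change of 0, which argues against the zeros being measured levels. All 320 values in the 8 siRNA libraries were exactly 0, so the level of Celf2 there is not known and a loss of the transcript cannot be read from them.

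Other splits of the same libraries were fitted for each count. For siHdac4 against siScramble 2 of 35 splits gave as many as the 48 loci, so chance was not excluded. The highest other split, siScramble library 1 with siHdac4 libraries 1 to 3, called 889, which points to a structure of the samples other than the groups. Without loci listed at 0, 6 of 35 splits gave as many as the 1 locus, with 899 as the highest other. For siBdnf against siScramble 1 of 35 splits gave as many as the 51 loci (highest other 2), but 43 of them are listed at 0 in all 4 siBdnf libraries, so this shows only that the zeros follow the groups. Without them limma called 0 loci, a count that every split reaches (35 of 35, highest other 2), so the splits could not test it. Without loci listed at 0, chance was not excluded for the loci under an unadjusted p of 0.05. These were 1826 in siHdac4 (highest other 4200) and 1581 in siBdnf (highest other 2124). For siHdac4 against siBdnf 1 of 35 splits gave as many as the 5 loci (highest other 1). The 2 of these that are listed at 0 in all 4 siBdnf libraries exceed that by themselves. Without loci listed at 0, chance was not excluded for the 1 locus left (2 of 35, highest other 1). No other split reached the 2863 loci under an unadjusted p of 0.05 there (1 of 35, highest other 1937). With these 2 groups alone in the fit none reached 152 loci, or 167 without those listed at 0 (1 of 35 and highest other 0 for each). A share of 1 of 35 is the smallest these splits can give. It cannot tell the siRNAs from any other difference between these groups of libraries. The 41 loci in both comparisons are all listed at 0 in the 8 siRNA libraries, so the regroupings (2 of 100 gave as many) show only that the zeros follow the groups. The highest other gave 533, which again points to a structure of the samples. For the gene lists chance was not excluded in any comparison: 5 lists in siHdac4 (15 of 35 splits, highest other 10), 1 in siBdnf (35 of 35, highest other 12) and 3 between the siRNA groups (21 of 35, highest other 7).

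In 15 of 201 groups of 4 libraries 1 value stood far from the other 3, where about 1 in 20 is reached by chance. In siScramble these were Foxj1 at 4.62 FPKM in library 3, Ndufs8 at 38.2 FPKM and Atp5e at 61.5 FPKM in library 1, and the ribosomal protein level at 5.31 in library 1. In siHdac4 they were Dynlrb2 at 3.49 FPKM and Otx2 at 0.487 FPKM in library 3, Zfp69 at 0.813 FPKM in library 1 and Etv1 at 41.8 FPKM in library 2. In siBdnf they were Insig1 at 24.7 FPKM, Zfp69 at 1.96 FPKM, Ntrk2 at 215 FPKM, Sugct at 5.38 FPKM and Atp5e at 48.2 FPKM in library 1, with Ndufs1 at 67.9 FPKM and Rpl11 at 9.55 FPKM in library 2.

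The effects of the 2 siRNA labels differed, by the direct limma contrast, for Hn1 (0.85), Sugct (−0.69) and Ssxb2 (−0.92). Leaving out single libraries ended the call in 9 of 12 fits for Hn1, 8 for Sugct and 6 for Ssxb2, and without loci listed at 0 Hn1 (adjusted p = 0.060) and Sugct (0.0583) did not pass. They also differed, by camera with a preset correlation, for oxidative phosphorylation (0.17), ribosomal proteins (0.14) and neocortex markers (0.089). With an estimated correlation none of the 3 lists passed (adjusted p = 0.573, 0.668 and 0.584).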

How the results depend on the processing

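Tests named here as added were chosen after the results were seen. Where a value moved, the cause was not tested unless stated. With loci listed at 0 left out (added), the counts were 1 in siHdac4, 0 in siBdnf, 1 between the siRNA groups and 0 in both comparisons, and 3 lists passed in siBdnf. Most calls against siScramble were such loci; between the siRNA groups 2 of 5 were, and Hn1 and Sugct crossed the threshold. Protein-coding loci alone (added) gave 1, 2 and 1 in both, with 8 and 2 lists, and the length and GC correction of such loci gave 1, 2 and 1; Celf2 and Gm10800, both listed at 0, were the calls left. Without siScramble libraries 1 and 3 (added) the counts were 79 in siHdac4 and 9 between the siRNA groups, 3 lists passed in siHdac4, the choroid plexus median in siBdnf reversed to 0.056 and Kcne2 to 0.10. Without siScramble libraries 3 and 4 (added) 2 lists passed in siHdac4 and 2 in siBdnf. Between the siRNA groups the count of 5 became 3 at 5 FPKM or more, 103 with library weights, 152 with the 2 groups alone, 2 at an adjusted p below 0.01 and 8 below 0.1. An estimated correlation between genes left 0 lists in siHdac4, 0 in siBdnf and 0 between the siRNA groups. For lists in siBdnf, a filter of 0.1 FPKM gave 2 and quantile scaling (added) 3, and an adjusted p below 0.1 (added) gave 9 in siHdac4, 5 in siBdnf and 5 between them. At an FDR below 0.01 the authors' deposited table gave 147 loci in siHdac4.

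Leaving out each library in turn gave 44 to 248 loci in siHdac4, 44 to 52 in siBdnf, 2 to 23 between the siRNA groups and 41 to 44 in both, with 248 and 23 without siScramble replicate 1. Lists (added) ranged from 3 to 7, 1 to 6 and 2 to 5. The lowest count in siHdac4, 3, came without siScramble replicate 3, and the highest in siBdnf, 6, without siScramble replicate 1. Bdnf in siBdnf ranged from −0.062 to −0.015, Hdac4 in siHdac4 from −0.031 to 0.15, in siBdnf from −0.059 to 0.12 and between the siRNA groups from −0.051 to 0.11. None of the Hdac4 values passed, and its sign reversed in siHdac4 without siScramble replicate 2 (−0.031) or siHdac4 replicate 2 (−0.013). In siBdnf it reversed without siScramble replicate 2 (−0.059) or siBdnf replicate 2 (−0.0165). Between the siRNA groups it reversed with library weights (−0.0098), without siHdac4 replicate 2 (−0.051) or siBdnf replicate 1 (−0.0205).

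The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at −0.077 to 0.24, and 2 of 12 libraries were closest to their own number. With the number as a block the counts were 47, 52, 4 and 41 in both, with 4, 1 and 3 lists, the interferon-stimulated list in siHdac4 being lost (adjusted p = 0.056). Over all alternatives, 1775 values of named genes stayed on their side of the threshold, 191 lost a call, 7 gained one and 6 reversed. The 1775 include genes not called in the planned fit, so they do not measure how often a call was kept. Of the called lists 200 stayed, 33 lost the call and 1 reversed. The gains were Rpl35 (adjusted p = 0.0192), Rpl32 (0.0273) and Cox6b1 (0.040) in siHdac4 without siScramble replicate 1, and Sparc in siBdnf without siScramble replicate 4 (0.0172). Dynlrb2 gained in siBdnf with the block (0.0498), and between the siRNA groups Rpsa with library weights (0.0448) and Ndufb11 with the 2 groups alone (0.0499). Centring and joint adjustment of deposited comparisons were not run between the siRNA groups, which the deposited tables do not compare, and the pseudocount on deposited fold changes was not run since lists were tested on library values.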

Other observations

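The tests in this part were chosen after the results were seen.

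Intronic loci, which lie inside introns of annotated genes, were lower in siHdac4 than in siBdnf as a class. The median deviation of 3343 intronic loci from their mean over the 12 libraries was −0.052, −0.085, −0.12 and −0.026 on the log2 scale in siHdac4 libraries 1 to 4 and 0.034, 0.048, 0.080 and 0.18 in siBdnf libraries 1 to 4. The difference was −0.16 (n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). In siScramble the values ran from −0.15 in library 1 to 0.10 in library 4. At an unadjusted p under 0.05, 769 of 795 intronic loci (96.7%) were lower in siHdac4, against 1150 of 2070 other loci. Loci are not independent replicates, and several intronic loci can lie in the same gene. Of the 152 loci called with these 2 groups alone in the fit, 51 were intronic, 49 of them lower in siHdac4, and 56 were protein-coding, 35 of them lower. No explanation was tested.

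Disp1, a regulator of hedgehog release, and Cln3, a lysosomal membrane protein, took 2 separate levels across libraries of both siRNA groups. Disp1 was at 11.9, 11.96 and 8.26 FPKM in siHdac4 libraries 1, 2 and 4 and at 17.2 and 12.3 FPKM in siBdnf libraries 2 and 4, and at most 3.53 FPKM in the other 7 libraries. Cln3 was at 8.02 FPKM in siHdac4 library 3 and at 8.39 and 7.24 FPKM in siBdnf libraries 1 and 4, and at most 2.39 FPKM elsewhere. Both were called higher in both comparisons in the authors' deposited table.

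Several other genes called higher in the authors' deposited table rested on 1 or 2 libraries. Fgf10, a growth factor, was at 12.2 FPKM in siHdac4 library 2 and at most 1.89 FPKM in the other 3, Eng, an endothelial receptor, at 11.02 FPKM in siHdac4 library 1 and at most 2.36 FPKM in the others, and Tac2, a neuropeptide of the habenula and hypothalamus, at 84.6 FPKM in siBdnf library 1, at most 1.92 FPKM in the others and 13.7 FPKM in siScramble library 1. Wtap, a subunit of the RNA methyltransferase complex, was at 19.1 and 47.8 FPKM in siHdac4 libraries 2 and 4 and at 2.36 and 2.05 FPKM in libraries 1 and 3. In contrast Rnf17, a tudor-domain protein, lay at 2.78, 3.20, 2.99 and 2.22 FPKM in siHdac4, above all 4 siScramble libraries (at most 1.97 FPKM). Apln, the ligand of the apelin receptor, lay at 5.32, 5.80, 4.64 and 5.02 FPKM in siBdnf, above all 4 siScramble libraries (at most 4.35 FPKM). In siHdac4 libraries 1 to 4 Apln was at 4.35, 2.76, 3.64 and 5.16 FPKM. Neither Rnf17 nor Apln was among the loci past the threshold in limma.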
